A study of Arabidopsis thaliana with 16 samples.

How the data were processed

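Each of 16 RNA samples from Arabidopsis roots was labelled with biotin as cRNA and measured on its own 1-colour Affymetrix 3' array. Per the submitters' processing notes, the signals came from Affymetrix Expression Console 1.3. The algorithm is not given in the sources used here. The deposited values are a linear intensity per probe set, scaled per array by the authors, since the mean without the lowest and highest 2% of probe sets was 500 on every array when checked. All 16 columns were used.

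The 16 arrays form 8 groups of 2 per the labels, for the presence or absence of DEX (2 µM), NAA (1 µM) and CHX (10 µM) over 4 h. The replicate numbers were not taken as pairs, since the deviations of equally numbered arrays from their group means correlated by only -0.05 to 0.06 across probe sets. Of 22810 probe sets, 64 control probe sets were left out of the tests, and 22746 were tested. The annotation at hand names 1 gene for 13513 of them, several for 503 and lists no gene for 8730, which are called unnamed. Unnamed probe sets with the largest changes were chosen after their values were seen. Names come from the array's probe-to-gene list, with symbols updated through the gene ID for 13436 probe sets from the TAIR10.1 assembly's gene table. Probe sets for several genes stay in the counts and are not named. A gene with several probe sets (144 genes) was named by the one with the highest mean.

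Values were taken as log2(intensity + 16), a scale that understates the changes of genes with a low level. A linear model with 1 mean per group was fitted over all 16 arrays with limma 3.58.1 in R 4.3.3, with the variance prior following the mean level (8 residual and 7.94 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. There were 10 planned comparisons: DEX in each of the 4 backgrounds, their average, NAA alone, NAA with CHX, CHX alone, and the interactions of DEX with NAA and of DEX with CHX. The interaction of NAA with CHX, and CHX in the arrays with DEX, were added after the data were seen. Changes are log2 differences with the model's SE, SDs are between the 2 replicates, and tests are 2-sided. With 2 arrays per group, their number limits the precision. The groups were too small for a test of single arrays that lie apart.

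Before the data were examined, 12 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists were VLCFA elongation, suberin cutin and wax, early auxin response, lateral root regulators, lateral root emergence, cell cycle, cytokinin response, Casparian strip, root hair, green tissue, rapid stress response and ribosome biogenesis. The 3 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over all 30 tests of list and comparison. Of these, 10 were called, 8 of them also with an estimated correlation, and limma's fry called 10. A further 11 lists were drawn up from the genes that the annotation names, before any change was looked at: cytosolic ribosomal proteins, Aux/IAA with GH3 and YUCCA, expansins and XTH, class III peroxidases, histones, UGT, GSTU, plastid-encoded genes, SWEET, BGLU and TBL. They made 110 tests, with 30 called by camera, 2 of them also with an estimated correlation, and 24 called by fry.

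Named are PUCHI, and for each comparison the 10 called genes with the largest rise and the 10 with the largest fall among those where both treated arrays lie beyond both control arrays (for the DEX average, where all 4 backgrounds changed the same way). Named as well are up to 20 members of the shared DEX set, up to 4 called members of each list and comparison (or up to 2 that were not called), and the 5 called genes with the largest interaction in each direction. The interaction values of NAA with CHX are those of PUCHI and of members of the early auxin and lateral root lists.

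The alternatives were quantile normalization, only the 60% of probe sets with the highest mean (13648), the replicate number as a block, no variance trend, an added minimum of a 2-fold change, pseudocounts of 1 and 64, only the 4 arrays compared (2 residual degrees of freedom), an estimated correlation or fry for lists, and leaving out each array. Quantile normalization moved the median change of all probe sets by under 0.1 in every comparison. Like the authors' scaling, it sets the arrays to a common level, so neither can show a shift of all transcripts. Rises and falls are relative to that level, which matters most for CHX and NAA. Splits of the arrays within each background into DEX and no DEX were drawn 100 times with a fixed seed.

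The fit was tested on 20 simulated data sets of 22746 probe sets, 200 of them changed. For 2 arrays against 2 it recovered 63.1% of changes of 1 and 97.0% of changes of 2 on the log2 scale, with 5.23% false calls. For the DEX average it recovered 97.0% and 100%, with 5.25% false calls. A list of 60 genes shifted by 0.3 was called in 20 of 20 runs and an unshifted list in 0. The simulated noise was independent between probe sets, and each change was equal in all 4 backgrounds. These runs therefore do not test lists whose genes vary together. Nor do they test lists as small as the fixed ones, with 3 to 7 measured members. In the real data DEX gave 3 to 8 calls per background and 18 on average. With fewer changes than the 200 simulated the adjusted threshold is stricter, so the recovered shares may not hold for DEX.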

Results

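Transcript levels were measured in roots of Arabidopsis seedlings that lacked working PUCHI, an AP2/ERF transcription factor of lateral root primordia, and carried PUCHI fused to a glucocorticoid receptor domain under its own regulatory region. In such a fusion, dexamethasone (DEX) lets the protein enter the nucleus. Seedlings 5 days old were treated for 4 h with or without 2 µM DEX, 1 µM naphthaleneacetic acid (NAA, a synthetic auxin) and 10 µM cycloheximide (CHX, an inhibitor of protein synthesis). All 8 combinations were made with 2 replicates each, and the mock contained 0.1% DMSO. The 16 arrays gave intensities for 22746 probe sets that were not controls, with a median of 7.58 to 7.68 on the log2 scale per array. Pearson's r across probe sets, which are not independent replicates, was 0.983 to 0.989 between the replicates of a group. No sample without the transgene was treated with DEX, so no background of DEX itself was measured here. The number of arrays limits the precision of every value below.

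PUCHI transcript (AT5G18560) had a mean of 7.80 ± 0.115 (SD, n = 2) on the log2 scale in the mock and of 10.80 ± 0.0849 (SD, n = 2) after NAA. It rose 7.99-fold with NAA (log2 change 3.0, SE 0.136, limma adjusted p 8.25e-11, n = 2 against 2). With CHX alone it rose by 0.96 (limma adjusted p 9.74e-06, n = 2 against 2). In the presence of CHX, NAA gave a PUCHI change of 0.04 (limma adjusted p 0.955, n = 2 against 2). The difference between the NAA changes without and with CHX was -2.95 (SE 0.192, limma adjusted p 2.19e-08). After DEX alone the PUCHI change was -0.82, which missed the threshold (limma adjusted p 0.0641, n = 2 against 2) and passed it after quantile normalization (0.0396) and with only the 60% of probe sets with the highest mean (0.0249), within a range of 0.0249 to 0.478 over 20 alternatives. The changes with DEX were 0.05 with NAA, -0.09 with CHX and -0.17 with both, and -0.26 on average (limma adjusted p 0.32). The probe set does not tell the transcript of the fusion gene from that of the mutant gene.

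**Figure D1:**
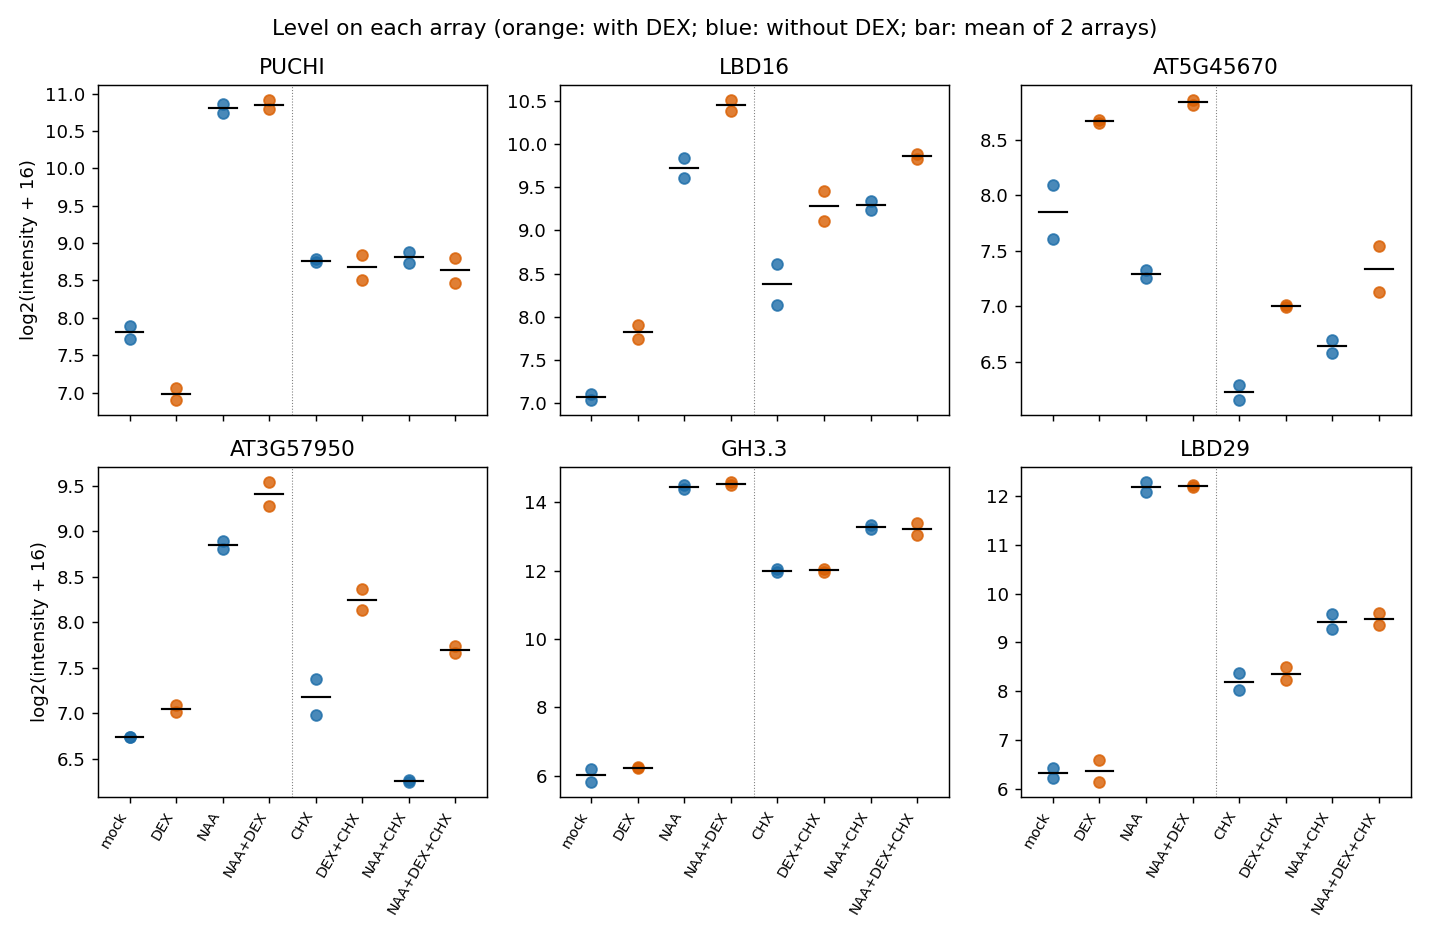
Level of 6 genes on each of the 16 arrays, as log2(intensity + 16) on the vertical axis, for the 8 treatment groups on the horizontal axis, with scales that differ between panels and do not start at 0. Each point is 1 array (orange with DEX, blue without), each bar the mean of 2 arrays, and the dotted line parts groups without and with CHX.

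The effect of DEX was asked as the average over the 4 backgrounds (8 arrays with DEX against 8 without), which bears on which transcripts respond to PUCHI-GR activation. AT5G45670, a GDSL esterase/lipase family gene, rose by 0.96 (SE 0.0935, limma adjusted p 0.000182). AT3G57950 rose by 0.85 (SE 0.0835, limma adjusted p 0.000182). LBD16 (AT2G42430), a LOB-domain transcription factor of lateral root initiation, rose by 0.74 (SE 0.0749, limma adjusted p 0.000197). The lipid-transfer family gene AT3G18280 rose by 0.44 (SE 0.0596, limma adjusted p 0.00371), and the class III peroxidase AT4G08780 rose by 0.63 (SE 0.11, limma adjusted p 0.0405). In total 15 probe sets rose and 3 fell, of which the annotation leaves 12 unnamed and gives several genes for 1. Among the unnamed probe sets the largest rises were 1.69 and 1.51 and the largest fall was -0.57. The call of AT4G08780 ended in 13 of the 16 fits that left out 1 array, with changes of 0.52 to 0.74. Without NAA replicate 1 the number of calls was 10 instead of 18, and the unnamed probe set with the largest fall missed the threshold (limma adjusted p 0.056), as it did without mock replicate 1 (0.0513).

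LBD16 had changes with DEX of 0.75 alone, 0.72 with NAA, 0.91 with CHX and 0.57 with both, none of which passed the test in its own background (limma adjusted p 0.242, 0.122, 0.0734 and 0.357, n = 2 against 2). Leaving out CHX replicate 2 gave LBD16 a change with CHX of 1.15 that passed (limma adjusted p 0.0135), and leaving out DEX+CHX replicate 2 gave 1.08 (0.0474). AT5G45670 changed by 0.81, 1.54, 0.78 and 0.70 in the same order, and AT3G57950 by 0.31, 0.56, 1.07 and 1.44. The value of AT3G57950 with CHX did not pass (limma adjusted p 0.0507), but did after quantile normalization at 1.12 (limma adjusted p 0.0381) and without CHX replicate 1 at 1.27 (0.0388). Of the fixed lateral root regulators, 4 of 26 were measured by name. For the DEX average 1 of them rose over all probe sets tested, LBD16, and 1 did when adjusted over the list alone. The list moved up in limma's camera test (adjusted p 0.00566), with an adjusted p of 0.103 with an estimated correlation. Its other measured members had values of 0.22 (CR4), 0.06 (LBD29) and -0.13 (BBM) that did not pass (limma adjusted p 0.781, 0.927 and 0.817). Of the early auxin response genes 7 of 23 were measured and none passed for the DEX average in limma, while 2 did when adjusted over the list alone. IAA20 had the value 0.30 and GH3.1 the value 0.19. This list was also called up by limma's camera (adjusted p 0.0402), with an adjusted p of 0.103 with an estimated correlation, and the call ended after quantile normalization (0.0729) and in 8 of the 16 fits that left out 1 array, with the highest adjusted p at 0.177.

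DEX without NAA or CHX was compared with the mock. No gene named by the annotation passed the test, and 3 unnamed probe sets rose and 2 fell. The largest rise of an unnamed probe set was 2.73 (SE 0.362, limma adjusted p 0.0136, n = 2 against 2), and its call ended without mock replicate 1 (2.36), DEX replicate 1 (2.68) or DEX replicate 2 (2.79). At an unadjusted p under 0.05 there were 1068 probe sets, where 1137 would arise by chance among independent probe sets. The count of 5 fell to 0 without the variance trend and to 0 with only the 4 arrays compared.

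With NAA present, DEX raised AT5G45670 by 1.54 (SE 0.187, limma adjusted p 0.00881, n = 2 against 2) and AT5G02990 fell by 1.70 (SE 0.275, limma adjusted p 0.0372, n = 2 against 2). In total 7 probe sets rose and 1 fell, 6 of them unnamed. The unnamed probe set with the largest rise, 1.88 (limma adjusted p 0.0229), also rose in the comparison with CHX. Without NAA+DEX replicate 1 no probe set passed, and without NAA replicate 1 AT5G45670 stood at 1.51 (limma adjusted p 0.1). The call of AT5G02990 ended without each of the 4 arrays (values from -1.92 to -1.48) and with a replicate block, and that of this unnamed probe set ended without NAA replicate 1 (1.68) or either NAA+DEX replicate (1.85 and 1.92).

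With CHX present, which addresses responses that need no new protein, DEX raised AT4G21780 by 2.06 (SE 0.223, limma adjusted p 0.000957, n = 2 against 2). The unnamed probe set that rose most with NAA rose by 2.06 here (limma adjusted p 0.00506), and another unnamed probe set fell by 1.60 (limma adjusted p 0.000957). These were the only 3 calls. The lateral root regulators had 0 of 4 called over all probe sets in limma and 2 when adjusted over the list alone, CR4 (the receptor kinase ACR4) at 1.07 and LBD16 at 0.91. The list moved up in limma's camera test (adjusted p 8.01e-05), also with an estimated correlation (adjusted p 0.0317). It was not called with DEX alone, with NAA or with both (limma's camera adjusted p 0.349, 0.261 and 0.378). There CR4 had values of 0.07, 0.04 and -0.30, and the difference of the DEX response with CHX was not called for the list (limma's camera adjusted p 0.24). The 2 CHX arrays are also used in NAA with CHX and in CHX alone, where CR4 changed by 1.57 and -1.86. A low CR4 level in these 2 arrays cannot be told apart from separate responses. AT4G21780 also rose with NAA against these CHX arrays. The call of the unnamed rising probe set ended without CHX replicate 1 (1.67) or DEX+CHX replicate 1 (1.90). The count was 8 without DEX+CHX replicate 2, and 0 with only the 4 arrays compared.

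With NAA and CHX present, DEX raised AT3G57950 by 1.44 (SE 0.167, limma adjusted p 0.00309, n = 2 against 2), AT1G68240 by 1.92 (SE 0.309, limma adjusted p 0.0454) and HRGP1 (a hydroxyproline-rich glycoprotein, on a probe set that may also match related sequences) by 0.70 (SE 0.106, limma adjusted p 0.0315). AT3G12010 fell by 0.73 (SE 0.119, limma adjusted p 0.0454). In total 5 probe sets rose and 2 fell. The calls of AT1G68240, HRGP1 and AT3G12010 each ended without any 1 of the 4 arrays (1.72 to 2.13, 0.64 to 0.77 and -0.80 to -0.66), and those of AT1G68240 and AT3G12010 also after quantile normalization or with a replicate block. The count was 2 without NAA+DEX+CHX replicate 1, 11 without NAA+CHX replicate 2 and 0 with only the 4 arrays compared.

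Of the other fixed gene lists, none had a member that passed the test with DEX, in the 4 backgrounds or on average. Adjusted over each list alone, the 2 measured of 15 cytokinin response genes passed for DEX with CHX, ARR15 at 0.89 and RR16 at 0.92. ARR15 also did with NAA at -0.98 and for the DEX by NAA interaction at -1.25. Over all probe sets the limma adjusted p was 0.54 for ARR15 and 0.578 for RR16 with CHX. For ARR15 it was 0.384 with NAA and 0.592 for the interaction. With NAA and CHX the DEX changes were -0.08 for ARR15 and -0.50 for RR16. Adjusted over its list alone, CML38 of the rapid stress list passed for DEX alone at 0.41, and IAA20 of the early auxin list with NAA at 0.73. The cell cycle and emergence lists had 1 measured gene each, so for them this is an unadjusted p. It was under 0.05 for AUR1 with NAA at 0.32 (limma adjusted p over all probe sets 0.513). The same held for AT5G14650 with NAA and CHX at -0.57 and for the DEX by CHX interaction at -0.58 (limma adjusted p over all probe sets 0.659 and 0.651). Over all 12 lists 28 of 217 genes were measured by name, and 1, 3, 2, 1 and 1 of them passed when all 28 were adjusted as 1 list, for DEX alone, with NAA, with CHX, with both and on average. The list of very-long-chain fatty acid elongation had 0 of 27 genes measured by name, as the annotation leaves 8730 of the 22746 probe sets unnamed. Suberin, cutin and wax had 2 of 31 and the lateral root emergence list 1 of 12. The 3 rapid stress response genes were not called as a list for the DEX average (limma's camera adjusted p 0.615).

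A set of probe sets called the same way with CHX, with NAA and CHX, and in at least 1 of the comparisons without CHX held 0 members in limma, where 2.05e-07 would be shared by independent lists. At an unadjusted p under 0.05 it held 25 (18 up, 7 down), where 3.43 would be shared by independent lists. Among the rises were AT5G45670, LBD16, AT3G18280 and AT3G57950, all called for the DEX average from the same values, and an unnamed probe set at 0.94 to 1.55. Among the falls were the plastid genes psaI and psbZ. Some members changed sign between backgrounds, such as AT4G14060 at -0.99 alone and 0.30 with NAA. The DEX comparisons use 1 variance estimate per probe set, so the lists are not independent. At the same threshold DEX alone and DEX with NAA shared 54 rises and 50 falls (16.9 and 21.1 by independent lists), beside 64 probe sets in opposite directions (38.7). DEX with CHX and DEX with both shared 77 rises and 84 falls (23.0 and 34.7), beside 51 in opposite directions (56.5). Across CHX states, DEX alone shared 24 rises and 26 falls with DEX with CHX (16.45 and 18.8), beside 52 opposite (35.6). With DEX with both it shared 26 and 21 (19.25 and 21.0), beside 57 opposite (40.6). DEX with NAA shared 45 and 42 with DEX with CHX (20.2 and 34.9), beside 60 opposite (53.2). With DEX with both it shared 48 and 35 (23.65 and 39.1), beside 67 opposite (61.0). The shared DEX set held 1 member with a pseudocount of 64, and 1 without CHX replicate 2. Across probe sets, which are not independent, r between the DEX changes of any 2 backgrounds was -0.02 to 0.05. Among the 100 probe sets with the smallest p in 1 background, 43 to 66 had the same sign in another, where 50 would by chance.

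Whether the DEX response differed with NAA or with CHX was tested as an interaction over all 16 arrays. No gene named by the annotation differed. For DEX by NAA 0 probe sets passed in limma, and 1334 had an unadjusted p under 0.05. For DEX by CHX 1 unnamed probe set passed, at -0.61 (SE 0.0801, limma adjusted p 0.0222). Its change with DEX was -0.64 with NAA and CHX (limma adjusted p 0.00465), a call that ended without NAA+DEX+CHX replicate 1 (-0.59). Its interaction call ended in 12 of the 16 fits that left out 1 array (-0.65 to -0.58 over all 16) and without the variance trend. Without DEX+CHX replicate 2 the count was 6.

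NAA against the mock, without DEX or CHX, shows the auxin response of these roots. GH3.3, an auxin-conjugating enzyme, rose by 8.43 (SE 0.123, limma adjusted p 9.44e-17, n = 2 against 2). The auxin-response repressor IAA29 rose by 6.0, LBD29 by 5.86 and GH3.1 by 5.80 (limma adjusted p 2.78e-13, 2.04e-13 and 4.94e-15). AT4G37295, AT5G17340, WES1 (GH3.5), AT1G30760, AT3G51410 and AT2G23060 rose by 5.34 to 4.15. The pectin methylesterase inhibitor family gene AT4G25250 fell by 5.79. AT4G30450, AT5G04120 and XTH21, a xyloglucan endotransglucosylase/hydrolase, fell with changes of -5.03, -4.69 and -4.67. AT4G30460, AT1G19900, AT2G34610, AT3G01260, AT3G45680 and AT2G41810 fell with changes of -4.56 to -3.81. In all 3093 probe sets rose and 2915 fell, 26.4% of those tested, and 798 and 970 of them changed at least 2-fold. The 3'/5' signal ratio of the GAPDH control, a sign of RNA integrity, was 1.12 ± 0.0384 (SD, n = 2) with NAA and 1.06 ± 0.00559 (SD, n = 2) in the mock.

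All 7 measured early auxin response genes rose with NAA, and 7 did when adjusted over the list alone (median 4.40). The list moved up in limma's camera (adjusted p 4.24e-16), also with an estimated correlation (adjusted p 0.000353). Besides those named, IAA30 rose by 4.05, HAT2 by 1.82 and IAA20 by 1.49. Of the 4 lateral root regulators 3 rose over all probe sets and 3 adjusted over the list alone, LBD29, LBD16 by 2.65 and BBM by 0.73 (limma's camera adjusted p 0.000149, also with an estimated correlation, adjusted p 0.0317). All 3 rapid stress response genes rose, and 3 did adjusted over the list alone, STZ by 1.40, WRKY53 by 1.26 and CML38 by 0.47 (limma's camera adjusted p 0.00223, also with an estimated correlation, adjusted p 0.0317). The call of CML38 ended without mock replicate 1 (0.47), mock replicate 2 (0.48) or NAA replicate 1 (0.32).

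Of the lists too small to test as sets, both measured root hair expansins fell with NAA, with changes of -0.72 for EXPA18 and -0.68 for EXPA7. Both measured ribosome biogenesis genes rose, the RNA helicase PRH75 by 0.78 and AT3G05060 by 0.39, and the call of AT3G05060 ended without mock replicate 2 (0.37), NAA replicate 1 (0.40) or NAA replicate 2 (0.37). The cytokinin response regulator RR16 fell by 1.60, the Casparian strip receptor kinase GSO1 fell by 0.58 and the polygalacturonase AT5G14650 of the emergence list rose by 1.2. Of the green tissue markers, Rubisco activase (RCA) fell by 0.55, a call that ended without mock replicate 2 (-0.51) or NAA replicate 2 (-0.47). The cell cycle list had its 1 measured gene, AUR1, and the suberin list its 2, short of the test over all probe sets. Adjusted over each list alone, the counts were 2, 2, 1, 1, 1, 2, 1 and 0 for root hair, ribosome biogenesis, cytokinin response, Casparian strip, emergence, green tissue, cell cycle and suberin. For emergence and cell cycle, with 1 measured gene each, this is an unadjusted p.

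NAA in the presence of CHX, against CHX, asks which auxin responses appear when protein synthesis is inhibited. Its CHX control arrays are also used in DEX with CHX and in CHX alone, so these comparisons are not independent. GH3.3 rose by 1.28 (SE 0.123, limma adjusted p 5.53e-05, n = 2 against 2), LBD29 by 1.23 (SE 0.164, limma adjusted p 0.00107), WES1 by 1.01 (limma adjusted p 0.000347) and IAA30 by 0.87 (limma adjusted p 0.002). The largest rises were those of AT4G23760 at 1.92, AT3G45680 at 1.90, AT2G15010 at 1.79 and AT4G21780 at 1.77. AT3G63095, AT1G31050, AT4G20500, CR4, AT3G25870 and AT4G11340 rose by 1.65 to 1.47. AT4G25250 fell by 2.1. The plastid gene psbA, AT2G07695 and AT2G11150 fell as well, with changes of -2.01, -1.90 and -1.78, and AT4G17470, AT4G29250, AT2G07110, AT5G35660, plastid atpH and AT1G33880 fell with changes of -1.62 to -1.47. A second probe set of AT1G31050 gave -0.35 and was not called. The intensity of the 25S ribosomal RNA control was 7292 ± 11.3 (SD, n = 2) with NAA and CHX and 9436 ± 954 (SD, n = 2) with CHX.

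In all 77 probe sets rose and 216 fell with NAA in the presence of CHX, of which 28 and 47 changed at least 2-fold. Of these 20 genes with the largest changes, 5 kept their call without any 1 of the 4 arrays (AT4G21780, AT1G31050, psbA, AT2G07695 and atpH) and 15 did not. The lost calls had adjusted p up to 0.246 in limma, and the value for AT4G25250 moved most, to -1.40 without NAA+CHX replicate 2. The count was 107 without NAA+CHX replicate 2 and 178 without NAA+CHX replicate 1, and 16 with only the 4 arrays compared.

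Of the early auxin response genes 6 of 7 rose with NAA in the presence of CHX, and 7 did when adjusted over the list alone (median 0.94). The list moved up in limma's camera (adjusted p 6.62e-17), also with an estimated correlation (adjusted p 0.000353). IAA20 rose by 1.39, IAA29 by 0.94 and GH3.1 by 0.59. The calls ended for IAA20 without NAA+CHX replicate 2 (1.23), for IAA29 without CHX replicate 1 (0.75) or either NAA+CHX replicate (0.86 and 1.02), and for GH3.1 without each of the 4 arrays (0.56 to 0.63). Of the lateral root regulators 3 of 4 rose, and 4 did adjusted over the list alone (limma's camera adjusted p 1.31e-08, also with an estimated correlation, adjusted p 0.0099). These were CR4 by 1.57, LBD29 and LBD16 by 0.92. The call of CR4 ended without NAA+CHX replicate 2 (1.49), and that of LBD16 without CHX replicate 1 (0.68) or NAA+CHX replicate 2 (0.86). The root hair expansin EXPA7 fell by 0.72 (ended without CHX replicate 1 at -0.64, CHX replicate 2 at -0.80 or NAA+CHX replicate 2 at -0.59), and 2 of the 2 root hair genes passed adjusted over the list alone. None of the 3 rapid stress response genes passed over all probe sets or adjusted over the list alone, and limma's camera gave an adjusted p of 0.662.

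**Figure D2:**
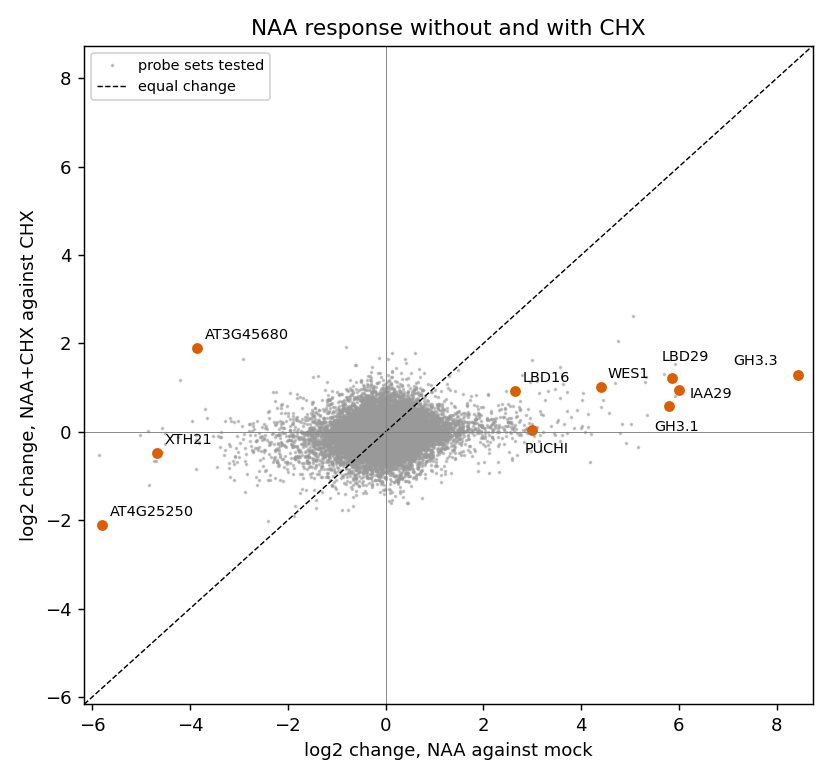
Log2 change with NAA against the mock (horizontal axis) and with NAA in the presence of CHX against CHX (vertical axis) for the 22746 probe sets, each a grey point. The dashed line marks equal change, and of the 10 genes marked in orange GH3.3 lies at 8.43 and 1.28, PUCHI at 3.0 and 0.04, and AT3G45680 at -3.85 and 1.90.

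The difference between the NAA responses without and with CHX was tested as an interaction that was added after the data were seen. It passed for 3210 probe sets, 1488 with a positive and 1722 with a negative value. The values were -7.15 for GH3.3, -5.21 for GH3.1, -5.06 for IAA29, -4.63 for LBD29, -3.39 for WES1, -3.17 for IAA30, -1.73 for LBD16 and -1.54 for HAT2 (limma adjusted p for GH3.3 3.1e-13, n = 4 against 4). CR4 had a positive value of 1.15, whose call ended in all 8 fits that left out 1 array (0.99 to 1.32) and with a replicate block. IAA20 and BBM had values of -0.09 and -0.34 that did not pass (limma adjusted p 0.9 and 0.451). Of the 3093 probe sets that rose with NAA, 1619 had a smaller response with CHX and 0 a larger one, and of the 2915 that fell, 1381 had a smaller fall and 1 a larger one. These counts share the mock and NAA arrays with the calls they start from, so chance alone makes the second response smaller. Between NAA alone and NAA with CHX, which share no array, 43 rises were common where 10.5 would be shared by independent lists. For falls the numbers were 155 and 27.7, and 20 probe sets were called in opposite directions where 39.2 would be, AT3G45680 among them.

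CHX against the mock gave the largest number of changes among the planned comparisons. AT1G10875 rose by 9.37 (SE 0.248, n = 2 against 2) from a mock mean of 4.14 ± 0.0394 (SD, n = 2), so low that the added 16 bounds the value, AT2G23270 by 9.13, and the MATE transporter family genes AT2G04050 and AT2G04070 by 9.06 and 8.88. AT3G54520 rose by 9.04, the AP2/ERF gene AT1G22810 by 8.92, the beta-glucosidase BGLU27 by 8.82, AT5G43450 by 8.64, AT2G37810 by 8.60 and AT1G74870 by 8.57. AT5G57785 fell by 7.86, and the methionine sulfoxide reductase MSRB5, AT1G13930 and AT4G23670 fell with changes of -7.77, -7.33 and -7.02. AT4G11190, the cysteine-rich peptide genes LCR69 and LCR68, AT3G53980, AT5G62210 and AT1G48750 fell with changes of -6.89 to -5.92. Each of these 20 genes passed in limma. In all 5866 probe sets rose and 6906 fell relative to the common array level, 56.2% of those tested. At least 2-fold changes numbered 3629 and 3746. The 3'/5' signal ratio of the ubiquitin control was 3.35 ± 0.41 (SD, n = 2) with CHX and 2.52 ± 0.261 (SD, n = 2) in the mock, while the ratio was lower with CHX for GAPDH (0.968 ± 0.0233 against 1.06 ± 0.00559) and for actin (2.42 ± 0.405 against 3.18 ± 0.389).

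All 3 rapid stress response genes rose with CHX, and 3 did adjusted over the list alone, STZ by 7.44, CML38 by 6.95 and WRKY53 by 6.37 (limma's camera adjusted p 0.000219, also with an estimated correlation, adjusted p 0.0209). All 7 early auxin response genes rose, and 7 did adjusted over the list alone, with GH3.3 at 5.98, GH3.1 at 4.82 and IAA30 at 3.52 (limma's camera adjusted p 8.01e-05, also with an estimated correlation, adjusted p 0.0152). Of the lateral root regulators LBD29 rose by 1.87, LBD16 by 1.3 and BBM by 0.98, and CR4 fell by 1.86, with 3 up and 1 down also adjusted over the list alone. Their list was not called by limma's camera (adjusted p 0.261). Both ribosome biogenesis genes fell, with changes of -1.23 for PRH75 and -1.0 for AT3G05060. AUR1 fell by 1.05, AT1G61590 of the Casparian strip list fell by 1.75, EXPA18 fell by 1.15 and RCA fell by 0.69. Of the cytokinin response regulators ARR15 rose by 1.29 and RR16 fell by 1.34. AT5G14650 fell by 1.03, a call that ended without mock replicate 1 (-0.78). Neither measured suberin gene passed over all probe sets or adjusted over the list alone.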

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

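The tests of the smaller NAA response under CHX were all chosen after that response was seen, while the counts over other splits of the arrays for the DEX interactions were planned. The interaction of NAA with CHX was not planned, and the 11 further gene lists were added with the data at hand, before any change was computed.

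The NAA response was smaller in the presence of CHX for 1619 of the rises and 1381 of the falls with NAA. In all 3210 probe sets passed the limma test of a difference in either direction. Among them were PUCHI at -2.95 and all 20 of the genes with the largest NAA changes. Of the fixed lists, GH3.3 had -7.15, GH3.1 -5.21, IAA29 -5.06, LBD29 -4.63, WES1 -3.39, IAA30 -3.17, LBD16 -1.73 and HAT2 -1.54. CR4 went the other way at 1.15, a call that ended with a replicate block (limma adjusted p 0.0511) and in all 8 fits that left out 1 array. IAA20 at -0.0925 and BBM at -0.338 did not pass (limma adjusted p 0.9 and 0.451). A ceiling of the array as the whole cause is argued against, since 65.2% of the 1619 affected rising probe sets were higher with NAA than with NAA and CHX by over 2 SE. These probe sets were picked on the same arrays, which by itself raises that share. Their median level with NAA and CHX was 8.97 (log2), where the highest value of each array was at least 14.9. A lack of NAA in the samples with both is argued against as well, since 6 of the 7 early auxin response genes rose there against CHX. Saturation of these genes by CHX itself cannot be told apart for the whole set, because 44.2% of the affected probe sets rose with CHX in the arrays with DEX, against 25.1% of all probe sets and 38.4% of the NAA rises that were not called smaller. It is argued against for the 1041 rising probe sets that CHX lowered there, whose median change with NAA was 0.0371 with CHX and 0.60 without, and the 770 not called for CHX there had 0.0359 and 0.73. These tests cover the rises only, and the 1381 smaller falls were not tested in this way. Of the 2915 falls with NAA, 1669 also fell with CHX in the arrays with DEX, where 912 would by independent lists. An effect of CHX itself on the falls therefore cannot be told apart. A need for new protein synthesis in the later NAA response may remain as a hypothesis, and it was not tested.

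The response to DEX differed with CHX for 1 unnamed probe set, at -0.61 in limma, and 11 of 100 splits of the arrays gave at least as many calls (real 1, highest other 7), so chance is not excluded. For the interaction of DEX with NAA, 0 probe sets passed in limma (1334 at an unadjusted p under 0.05), so that 100 of 100 splits gave at least as many by construction, which decides nothing about chance.

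Cytosolic ribosomal proteins differed in their DEX response with NAA as a list in limma's camera (adjusted p 1.18e-06, up, 0 of 105 members called), with an adjusted p of 0.205 with an estimated correlation. Histones did so as well (limma's camera adjusted p 0.0396, up, 0 of 6 members called, adjusted p 0.38 with an estimated correlation), a call that ended after quantile normalization (adjusted p 0.0521) and in 8 of the 16 fits that left out 1 array. Class III peroxidases differed in their DEX response with CHX (limma's camera adjusted p 0.0116, down, 0 of 55 members called, adjusted p 0.221 with an estimated correlation), a call that ended in 4 of those 16 fits (adjusted p up to 0.0664). The BGLU list did so in the other direction (limma's camera adjusted p 0.0396, up, 0 of 20 members called, adjusted p 0.299 with an estimated correlation), and this call ended after quantile normalization (adjusted p 0.0632) and in 9 of the 16 fits.

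Among the control probe sets, which no comparison uses, the 3'/5' signal ratio of GAPDH was 1.12 with NAA, 1.16 with NAA and DEX and 1.23 with NAA, DEX and CHX, above 1.06 in the mock (means of 2 arrays). The same ratio of ubiquitin was 3.35 with CHX, 3.21 with DEX and CHX and 3.12 with NAA and CHX, above 2.52 in the mock (means of 2 arrays). In the same order GAPDH gave 0.968, 0.967 and 1.08 beside 1.06 in the mock. Actin gave 2.42, 2.53 and 2.88, below 3.18 in the mock. With NAA, DEX and CHX the mean ratio was 2.905 for ubiquitin and 3.4 for actin, both above the mock mean.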

How the results depend on the processing

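The alternatives for the NAA by CHX interaction were chosen after seeing the data and those for the further gene lists with the data at hand, and all others before. Counts of probe sets called kept within 1.5 times their value under every alternative not given here, and the cause of a change was not tested unless stated. Quantile normalization gave 8 for DEX alone (instead of 5), 18 for DEX with NAA (instead of 8) and 4 for DEX with NAA and CHX (instead of 7). With only the 60% of probe sets with the highest mean, the counts were 8 for DEX alone, 13 for DEX with NAA and 5 for DEX by CHX (instead of 1). A replicate block gave 4 for DEX with NAA and 4 for DEX with NAA and CHX. Without the variance trend they were 0 for DEX alone, 11 for DEX with CHX (instead of 3), 114 for NAA with CHX (instead of 293) and 0 for DEX by CHX. A 2-fold minimum, which by construction can only remove calls, left 5 for DEX with NAA, 4 for DEX with NAA and CHX, 4 for the DEX average (instead of 18), 1768 for NAA alone (instead of 6008), 75 for NAA with CHX, 7375 for CHX alone (instead of 12772), 0 for DEX by CHX and 1498 for NAA by CHX (instead of 3210). A pseudocount of 1 gave 17 for DEX alone, 40 for DEX with NAA, 9 for DEX with CHX, 12 for DEX with NAA and CHX, 3 for DEX by NAA (instead of 0) and 5 for DEX by CHX. A pseudocount of 64 gave 1 for DEX alone, 2 for DEX with NAA, 7 for DEX with CHX and 1 for the shared DEX set (instead of 0). With only the 4 arrays compared, and so 2 residual degrees of freedom, the 4 DEX comparisons gave 0 and NAA with CHX gave 16. Leaving out 1 array, with the lone array of its group assumed to vary like the other groups, gave 2 to 9 for DEX alone, 0 to 11 for DEX with NAA, 3 to 8 for DEX with CHX, 2 to 11 for DEX with NAA and CHX, 10 to 22 for the DEX average, 4382 to 4687 for NAA alone, 107 to 178 for NAA with CHX, 11512 to 11781 for CHX alone, 0 to 6 for DEX by CHX, 2395 to 2803 for NAA by CHX and 0 to 1 for the shared DEX set. The count for DEX by NAA stayed at 0 in limma in these fits, with 1334 at an unadjusted p under 0.05 in the full fit. The fixed lists gave 9 to 11 calls and the further lists 20 to 31, and with an estimated correlation the further lists gave 2 (instead of 30). The change of PUCHI turned its sign in fits that left out 1 array for DEX with NAA (-0.0104 to 0.114), DEX with CHX (-0.256 to 0.0755) and NAA with CHX (-0.0283 to 0.116), none of them called.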

Other observations

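The tests of causes for the plastid-encoded genes were chosen after their change was seen. The 11 further gene lists were added with the data at hand, before any change was computed, and the splits for the DEX average and for the fixed lists were planned.

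Of 105 measured cytosolic ribosomal protein genes, 100 fell with CHX (median -1.67, limma's camera adjusted p 3.35e-27, also with an estimated correlation, adjusted p 0.0372). AT4G25890 fell by 3.81 and AT2G37600 fell by 3.28 (n = 2 against 2). With NAA, 17 of the 105 rose, AT5G39850 by 1.42 and AT5G59240 by 0.98, and the list moved up (limma's camera adjusted p 0.0466, adjusted p 0.507 with an estimated correlation), a call that ended in 6 of the 16 fits that left out 1 array. The list was also called for DEX alone, down, and for DEX with NAA, up, with 0 members called each time in limma. These calls had limma's camera adjusted p 8.33e-06 and 7.72e-05, adjusted p 0.221 and 0.293 with an estimated correlation, and ended after quantile normalization (adjusted p 0.0521 and 0.114).

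With NAA, 8 of the 16 Aux/IAA, GH3 and YUCCA genes rose and 1 fell (limma's camera adjusted p 8.33e-06, also with an estimated correlation, adjusted p 0.0372), and 6 of the 16 are in the early auxin list as well. Of 55 class III peroxidases 18 fell and 6 rose, with AT3G01190 at -3.0 and AT4G30170 at -2.87 (limma's camera adjusted p 0.00359, adjusted p 0.205 with an estimated correlation). Of 27 expansins and XTH genes 12 fell and 5 rose, with EXPB1 at -2.75, XTH32 at -2.49 and EXPA20 at 2.44 (limma's camera adjusted p 0.048, adjusted p 0.299 with an estimated correlation). The expansin and XTH call ended with a replicate block (limma's camera adjusted p 0.0509), after quantile normalization (0.0592) and in 11 of the 16 fits that left out 1 array. UDP-glycosyltransferases (18 of 47 fell, 3 rose, UGT74B1 at -1.79) had a limma's camera adjusted p of 0.00795 and an adjusted p of 0.143 with an estimated correlation. Of the GSTU glutathione transferases 5 of 11 fell and 1 rose, with GSTU28 at -3.03 and GSTU26 at -2.01 (limma's camera adjusted p 0.0197, adjusted p 0.295 with an estimated correlation). TBL genes (8 of 22 fell, 1 rose, TBL19 at -1.72) had a limma's camera adjusted p of 0.0073 and an adjusted p of 0.205 with an estimated correlation. SWEET sugar transporters (4 of 14 fell, SWEET14 at -1.90) had a limma's camera adjusted p of 0.0396 and an adjusted p of 0.221 with an estimated correlation, and the call ended in 2 of those 16 fits.

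With CHX, 16 of the class III peroxidases rose and 22 fell, with AT5G39580 at 7.45, AT1G14550 at 7.21 and AT3G49960 at -4.08, and limma's camera, whose direction was down, did not call them (adjusted p 0.733) beside a median of 0.0037 and a mean of 0.0805. Of 20 BGLU genes 7 rose and 1 fell, with BGLU31 at 7.30 and BGLU32 at 7.22 beside BGLU27 (limma's camera adjusted p 0.14). Of 6 histone genes 5 rose, AT2G37470 by 1.40 and HTB2 by 0.81 (limma's camera adjusted p 0.0561).

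Averaged over the backgrounds, 59 of 64 plastid-encoded transcripts were lower with DEX (median -0.17), ndhJ at -0.87 and petD at -0.78. None passed over all probe sets in limma, where 1581 of all probe sets had an unadjusted p under 0.05, and 15 did when adjusted over the list alone. Limma's camera called the list (adjusted p 1.14e-14), with an adjusted p of 0.205 with an estimated correlation. The fall was uneven: the median plastid-encoded level per array changed with DEX by -0.26 alone, -0.29 with NAA, -0.05 with CHX and -0.25 with both. The same list fell with CHX (44 of 64 fell, rbcL at -2.13) and with NAA (20 fell and 1 rose, psbA at -2.41), with limma's camera adjusted p 2.32e-05 and 8.33e-06 and an adjusted p of 0.381 with an estimated correlation for both. Beside these falls, the 25S ribosomal RNA control had an intensity of 9436 ± 954 with CHX and 10740 ± 912 with NAA against 13650 ± 339 in the mock (SD, n = 2), and of the green tissue markers RCA fell by 0.69 and by 0.55 while LHCB4.1 had values of 0.17 and -0.57 that did not pass. With NAA in the presence of CHX 59 of the 64 were lower and 7 fell (median -0.43, limma's camera adjusted p 5.82e-15, adjusted p 0.205 with an estimated correlation), beside a 25S control of 7292 ± 11.3 against 9436 ± 954 with CHX (SD, n = 2).

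For the lower plastid-encoded level with DEX, 12 of the 648 splits of the arrays within each background gave a mean difference as far from 0 (real -0.21, highest other 0.29, exact permutation p 0.0185). The list was picked from 11 for this change, and p times 11 is 0.204, so chance cannot be told apart. Less green tissue in the DEX samples as the cause is argued against only on 2 of 13 markers, and only for an equal log2 fall of both. The nuclear genes LHCB4.1 and RCA had a mean value of 0.0656 (SE 0.0869, SE of the difference from the plastid change 0.0989). A smaller loss of green tissue cannot be told apart. Less RNA without a poly(A) tail as the cause cannot be told apart. The 25S ribosomal RNA control had a value of -0.0714 (SE of the difference 0.0491), but that test assumes equal log2 falls of both. With CHX the median plastid-encoded level was 8.196 against 9.379 in the mock (log2), beside 25S intensities of 9436 and 13650, a smaller log2 fall. An effect of DEX itself without the transgene may remain, and it was not tested.

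For the DEX average, 1 of 100 splits gave at least as many called probe sets, the real one (real 18, highest other 8), so chance is excluded at 0.05. For the fixed lists called for the DEX average 3 of 100 splits gave as many (real 2, highest other 2). That share lies under the planned limit of 0.05, as does that of the DEX average. Only 100 of the 648 possible splits were drawn for both, and for the lists other splits tied with the real one. Chance is therefore not excluded for the number of lists called. Neither call holds with an estimated correlation (adjusted p 0.103 for both the lateral root regulators and the early auxin response genes in limma's camera), and the early auxin call also ended after quantile normalization (adjusted p 0.0729) and in 8 of the 16 fits that left out 1 array.

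The bioB hybridisation control gave 68.0, 68.3 and 107 on its 3 probe sets on NAA replicate 2, where the other 15 arrays lay between 323 and 823, while the bioC control on that array, at 1770, lay within the 1274 to 2265 of the others.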
